A study of Homo sapiens with 24 samples.

How the data were processed

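RNA was measured in 24 samples of the human colorectal cancer lines HCT15 and HT115, both of which carry loss-of-function mutations of the kinase MLK4 per the labels. Each line came in 2 engineered versions, with MLK4 inducible by tetracycline either as wild type (WT) or as a mutant form, Y330H in HCT15 and E314K in HT115. Each version was sampled 3 times with a Tet tag in the labels (24 h of tetracycline) and 3 times without it, which makes 8 groups of 3 arrays. The labels do not say what the samples without the tag received, and these are called untagged. Nothing in the labels says whether replicates came from separate cultures, so p-values measure only the spread between these samples, which may be technical. RNA was amplified by a whole-transcriptome method from NuGEN and hybridised to Affymetrix U133 Plus arrays per the labels' protocols. The deposited values are log2 signals per probe set, made by the submitters with RMA in Affymetrix Power Tools per the submitters' processing notes. No version of either is given in the sources used here, and neither is a detection call.

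The array medians of the deposited log2 values fell into separate scales. The 6 HT115 WT arrays had medians from 5.55 to 5.61, and the other 18 arrays had medians from 6.38 to 6.48. The mean median of the HT115 WT arrays was lower by 0.858, shown here as a difference of -0.858. The table therefore appears to join sets normalized separately, and levels of HT115 WT arrays were not compared with levels of other arrays. The planned baseline comparison of HT115 WT with HT115 E314K was not made for this reason. Differences between inductions that involve HT115 WT compare changes taken within each scale.

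Of 54675 probe sets, 41097 had exactly 1 gene symbol in the platform annotation, 1801 had several and 11777 were unnamed here. Of the 62 control probe sets 6 had a single gene symbol, which left 13522 probe sets without a single symbol that were not controls. The gene number of 41043 of the named probe sets was found in the RefSeq gene table (assembly GRCh38.p14), and no symbol needed an update. Each gene was represented by its brightest probe set over all 24 arrays, which gave 19775 genes. No filter on dim probe sets was applied. Genes of the Y chromosome were tested but are not named.

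Changes were tested on the log2 scale with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes without trend). All 24 arrays entered 1 fit of 8 group means, with 16 residual and 4.83 prior degrees of freedom. The comparisons were the 4 inductions (Tet minus untagged), the differences between inductions within each line and between the WT inductions, and HCT15 WT against Y330H in untagged arrays. A gene was called at a Benjamini-Hochberg adjusted p under 0.05 over the genes of its comparison, and every adjusted p of a gene printed below is from this limma fit unless the replicate block is named. Errors of changes are standard errors of that fit. Gene lists were tested with camera at its preset correlation of 0.01, adjusted over 34 lists fixed before the data were examined, and again with an estimated correlation. The number of arrays, 3 per group, limits the precision of every value.

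Before the data were examined, the genes to be named were fixed by rule. MAP3K21, JUN, CDKN1A, CDKN2B, MAPK8 and MAPK9 were named in every induction. The 10 genes with the largest rise and the 10 with the largest fall were named per induction, among called genes whose Tet and untagged arrays did not overlap, and per difference of inductions within a line among called genes. In the baseline and between-line comparisons 5 per direction were named. Where no gene was called, the 5 genes with the smallest p were named. From a gene list up to 4 called members were named, or up to 2 with the smallest p.

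The replicate numbers of the labels were tested as pairs. Deviations from the group means correlated between the Tet and untagged array of the same number in HCT15 WT (r of 0.581, 0.488 and 0.416 across genes) and in HCT15 Y330H (0.767, 0.618 and 0.310). The repeat numbers in the labels and this check were taken as pairing the HCT15 arrays, and the fit with the replicate number as a block (8 residual degrees of freedom) is given beside HCT15 results where it changes a call or moves a count by over 1.5 times. The HT115 arrays did not meet this check.

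The scripts were tested on simulated data drawn from the gene means and residual SDs, with 67 genes changed 1.5-fold, 67 changed 2-fold and 66 changed 4-fold among 19775 per induction. For the HCT15 WT induction, 38.8% of genes changed 1.5-fold, 88.1% of those changed 2-fold and 98.5% of those changed 4-fold were called, with 8 false calls among 158. The corresponding shares were 38.8%, 95.5% and 100% for the HT115 WT induction, 37.3%, 89.6% and 98.5% for HCT15 Y330H, and 55.2%, 82.1% and 100% for HT115 E314K. Each gene was given the same normal spread in all groups, so these shares differ between inductions only through the random draw. In the data the spread was unequal, with a median gene SD of 0.174 in untagged HCT15 WT and 0.118 in untagged HT115 WT arrays. The shares and false calls therefore need not hold for any single induction. When arrays of the same number were given a shared deviation, the share of genes called at 2-fold in HCT15 WT was 65.7% without and 86.6% with the replicate block. That deviation was as large as the residual SD and was added to it in both lines. The simulated spread was thus larger than that of the data, and the fall from 88.1% includes this added spread. Alternatives were the replicate block, quantile normalization across the 24 arrays, centring each array on its median, the brighter genes only, all probe sets, the mean of a gene's probe sets, only the arrays of a comparison, eBayes with trend and robust, arrayWeights and leaving out each array in turn. Gene lists were also tested with fry and with the block.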

Results

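Genome-wide expression was measured in HCT15 and HT115 cells in which MLK4 was induced with tetracycline for 24 h. MLK4, now named MAP3K21, is a mixed-lineage kinase that acts upstream of the JNK kinases. The study asked what restoring the wild-type kinase changes in colon cancer cells whose own MLK4 has lost function, with the series title pointing to JNK, JUN and the cell cycle inhibitors p21 (CDKN1A) and p15 (CDKN2B). Induction of the mutant forms Y330H and E314K served as the control. Each of the 8 groups held 3 arrays, and all group values below are means over n = 3 arrays on the RMA log2 scale. Arrays of a group correlated with each other at r of 0.986 or higher over probe sets. The difference between the 3' and 5' control probe sets of ACTB, a sign of RNA integrity, was 0.728 ± 0.388 (SD, n = 3) in untagged and 0.591 ± 0.304 in Tet-tagged HCT15 WT arrays. In HCT15 Y330H it was 0.429 ± 0.027 and 0.430 ± 0.085, and the means of the HT115 groups lay between 0.355 and 0.575. The high values in HCT15 WT came from the 2 arrays numbered 1.

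The induced gene was represented by a single probe set for MAP3K21, which lies on chromosome 1 from 233327724 to 233385148 (GRCh38.p14). Its level did not pass the test in any induction. The log2 change was -0.15 (SE 0.13, adjusted p = 0.797) with WT in HCT15 and -0.19 (SE 0.13, adjusted p = 0.854) with WT in HT115. With the mutant forms it was 0.08 in HCT15 and 0.02 in HT115, both with an SE of 0.13. The position of the probe set within the transcript is not given in the sources used here. A probe set outside the induced cDNA would not see the induction, so this value does not check the labels.

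Induction of wild-type MLK4 in HCT15 was followed by a rise of 121 genes and a fall of 17 among 19775 tested, and 50 of the rises were at least 2-fold. CPA4, a secreted carboxypeptidase, rose most, by 4.81 on the log2 scale (SE 0.40, 28.1-fold), from a level of 5.88 ± 0.20 to 10.69 ± 0.32 (SD, n = 3). Of the hair keratin-associated proteins, KRTAP4-1 rose by 3.36, KRTAP3-1 by 3.29 and KRTAP3-2 by 3.09, although near-identical members of this family can share probe signal and KRTAP3-2 had an SD of 2.45 in the Tet-tagged arrays. These were the only 3 called higher of 34 measured genes of the family, whose median change was -0.035. GPRC5A, a retinoic acid-induced receptor, rose by 2.91 and the scaffold protein AKAP12 by 2.31. S100A2, a calcium-binding protein of squamous epithelia, rose by 2.14 (SE 0.24, adjusted p = 5e-05). The transcription factor ETS1 rose by 2.07, the membrane protein MALL by 1.71 and the cytokine IL18 by 1.58. Among called genes whose Tet and untagged arrays did not overlap, the largest falls were in FGFBP1, a carrier of fibroblast growth factors, which fell by 2.06 (SE 0.39), in the iron-binding protein PIR by 1.30, in the receptor of double-stranded RNA TLR3 by 1.23 and in the protease PRSS23 by 1.21. ARID5B, HCFC1R1, ERAP2, TM7SF2, ZNF117 and SP5 fell by between 0.72 and 1.01. With the pairs as a replicate block the count was 961 (621 higher and 340 lower), which held all 138 genes. It was 6 when only the 6 HCT15 WT arrays were fitted and 1438 with arrayWeights. Without single arrays it was 50 (Tet number 1), 62 (untagged number 2), 58 (Tet number 2), 74 (untagged number 3) and 257 (Tet number 3), and it was 35 without both arrays numbered 1.

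**Figure D1:**
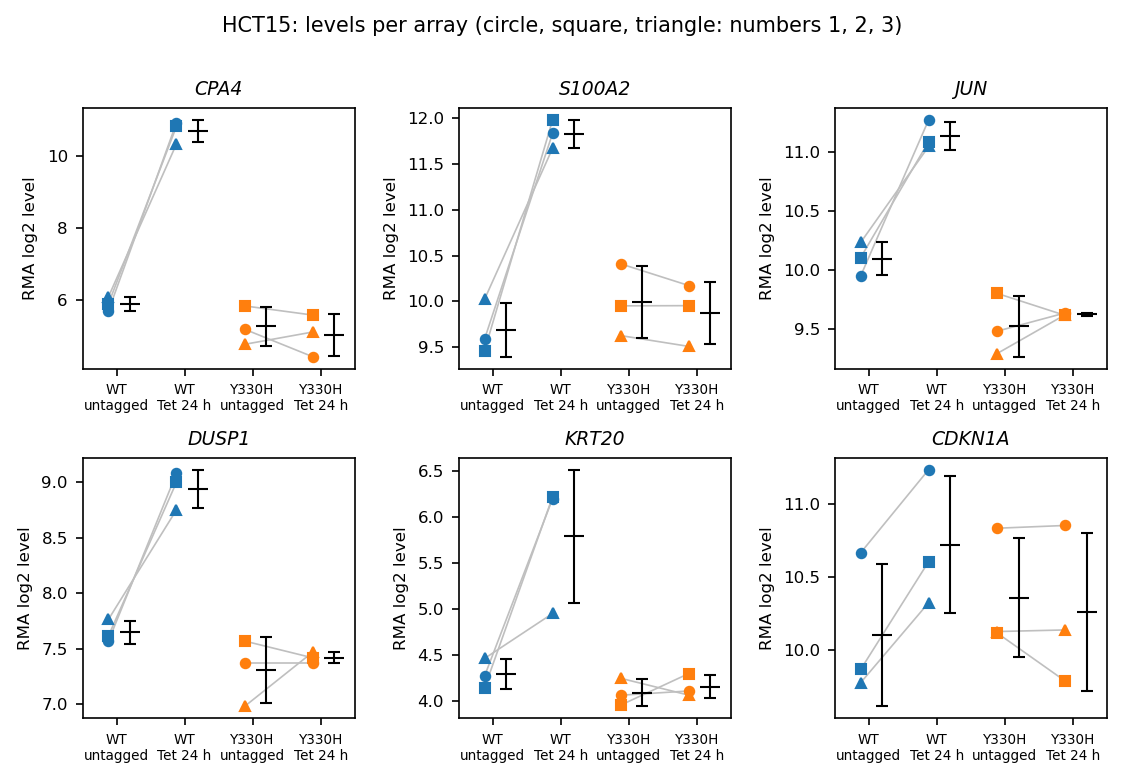
RMA log2 levels of 6 genes (vertical axes, each with its own range) in the 4 HCT15 groups, 1 point per array with lines joining arrays of the same number, and bars for the mean and SD of n = 3 arrays. CPA4 lies at 10.69 ± 0.32 in the Tet-tagged WT arrays against 5.88 ± 0.20 in the untagged ones, and CDKN1A is higher in the Tet-tagged WT array of each of the 3 pairs.

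The genes named in the study's title behaved unequally in HCT15. JUN, the AP-1 subunit that JNK phosphorylates, rose by 1.04 (SE 0.16, 2.06-fold, adjusted p = 0.00167) with wild-type MLK4. CDKN1A, which codes for p21, had a change of 0.62 (SE 0.31, adjusted p = 0.548) that did not pass the test. CDKN1A was higher in each of the 3 pairs, by 0.57, 0.74 and 0.55, and passed with the replicate block (adjusted p = 0.00255). CDKN2B, which codes for p15, had a change of 0.10 (SE 0.15, adjusted p = 0.888) at a low level of 5.27 ± 0.18 in Tet-tagged arrays. The JNK genes MAPK8 and MAPK9 had changes of 0.02 and -0.16, with adjusted p of 0.980 and 0.687.

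Among the gene lists in HCT15 with wild-type MLK4, the AP-1 lists stood out. Of 24 measured AP-1 and immediate early target genes, 4 rose over all genes tested and 10 adjusted over the list alone, and none fell. They were DUSP10 (by 1.31) and DUSP1 (by 1.29), phosphatases that inactivate JNK and other MAP kinases, the transcription factor KLF6 (2.29-fold) and the urokinase receptor PLAUR (by 1.13). The list shifted upward with a median change of 0.38 (camera adjusted p = 4.2e-18, and adjusted p = 0.00214 with an estimated correlation). Of 16 AP-1 family transcription factors, JUN and MAFG (by 0.40) rose over all genes and 7 rose adjusted over the list alone. That list also shifted upward (adjusted p = 5e-10, and adjusted p = 0.0035 with an estimated correlation). Of the 14 lists called in this induction, only the AP-1 lists were called with an estimated correlation. The replicate block called 16 lists, adding p53 targets (adjusted p = 0.0088) and, downward, metallothioneins (adjusted p = 0.022). Neither of these was called with an estimated correlation in the fit without the block.

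The remaining called lists in HCT15 with WT had few or no called members. The ERK feedback list shifted upward, with MYC rising by 0.53 as its called member and 7 rises and 1 fall adjusted over the list alone (adjusted p = 2.9e-06, and adjusted p = 0.139 with an estimated correlation). The list of integrated stress response genes under ATF4 had a median of 0.30 with no called member of 34, and 2 adjusted over the list alone. PPP1R15A, which restores translation after stress, had a change of 0.79 (adjusted p = 0.0713, and 0.013 with the replicate block) and the amino acid transporter chain SLC3A2 one of 0.56 (adjusted p = 0.0825, and 0.0017 with the replicate block). This list's adjusted p was 1.6e-07, and the adjusted p was 0.380 with an estimated correlation. Downward shifts were found for cholesterol biosynthesis, where IDI1 fell by 0.56 and 7 genes fell adjusted over the list alone (median -0.35, adjusted p = 1.5e-08, and adjusted p = 0.160 with an estimated correlation), and for interferon-stimulated genes, where IFIT1 had a change of -1.07 with an adjusted p of 0.0889 (0.0107 with the replicate block) and 5 genes fell adjusted over the list alone (median -0.21, adjusted p = 0.00028, and adjusted p = 0.139 with an estimated correlation). The list of G2/M and mitosis genes had no called member of 30 and a median of -0.15 (adjusted p = 6.6e-05, and adjusted p = 0.173 with an estimated correlation). The adjusted p was 0.0112 for unfolded protein response genes, downward (0.508 as adjusted p with an estimated correlation). For the Wnt and stem cell list, also downward, it was 0.0112 (adjusted p = 0.306 with an estimated correlation), and this list held both a rise of the adhesion receptor CD44 by 1.25 and a fall of the Wnt target SP5, with 1 rise and 8 falls adjusted over the list alone. Goblet cell markers shifted downward with an adjusted p of 0.0084 (adjusted p = 0.380 with an estimated correlation). Upward shifts with adjusted p of 0.0215 for YAP/TEAD targets, where AXL rose by 0.72, 0.0353 for apoptosis regulators, 0.0201 for mitochondrial ribosomal proteins and 0.0018 for ribosome biogenesis genes likewise had no call with an estimated correlation (adjusted p of 0.160, 0.160, 0.508 and 0.539).

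Members of lists that did not shift also changed in HCT15 with WT. The intestinal keratin KRT20 rose 2.82-fold (adjusted p = 0.00574) in an enterocyte list that had a median of -0.09 and no shift (adjusted p = 0.980, camera direction upward), and KRT19 rose by 0.70. KRT20 went from low levels of 4.27 to 6.20 and 4.14 to 6.22 in the pairs numbered 1 and 2, but only from 4.46 to 4.95 in number 3. It kept its call in 12 of 16 alternatives. NDRG1 of the hypoxia list rose by 1.13 and PLK3 of the p53 target list by 0.76, while BMP4 fell by 0.68. G1/S and DNA replication genes had no called member of 30 and no shift (adjusted p = 0.277). Markers of fibroblasts, leukocytes, endothelium and neural or muscle cells, which could mark other cell types, held no called gene and had adjusted p of 0.277, 0.463, 0.192 and 0.192.

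No gene was called by limma when Y330H was induced in HCT15, with 614 genes at an unadjusted p under 0.05 (3.1% of genes) and a smallest adjusted p of 1.00. The replicate block also called 0. The 5 genes with the smallest p were GIP, LINC02380, ADGRG4, LINC01210 and SLC7A9, with changes from -0.77 to -0.53, none past the threshold. JUN had a change of 0.10 (SE 0.16), CDKN1A of -0.10 (SE 0.31), CDKN2B of -0.01, MAPK8 of -0.03 and MAPK9 of 0.02. None of the 34 lists was called, whereas the ATF4 list was called upward with the replicate block (adjusted p = 0.013). Without the block, 0 lists were called with an estimated correlation or with fry. The 121 genes that rose with WT had a median change of 0.01 with Y330H, against 0.87 with WT.

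The difference between the HCT15 inductions was tested directly, which removes what tetracycline and the mutant protein share with wild type. It called 12 genes, all with a larger change with WT. They included CPA4 (difference of 5.04, SE 0.57, adjusted p = 0.00032), KRTAP3-1 (3.34), KRTAP4-1 (3.26), GPRC5A (2.94), S100A2 (2.26) and the actin-binding protein CORO2B (1.45). The chromatin protein HMGA2 (1.32), the actin-oxidising enzyme MICAL2 (1.21), DUSP1 (1.18) and the matrix proteoglycan BCAN (1.00) were called as well. Of 22 alternatives, HMGA2 and MICAL2 kept the call in 11 each and BCAN in 12. The lowest difference among these alternatives was 0.451 for HMGA2 and 0.236 for BCAN. For JUN the difference was 0.95 (SE 0.23, adjusted p = 0.198) and for CDKN1A 0.72 (SE 0.44, adjusted p = 1.00). Both passed with the replicate block (adjusted p of 0.0202 and 0.0242), which called 189 genes (133 higher and 56 lower). The upward shifts of the AP-1 target and AP-1 family lists also differed between the forms (adjusted p of 2.6e-11 and 1.7e-06, and adjusted p of 0.0212 and 0.0284 with an estimated correlation). The other 8 of 10 called lists, among them cholesterol biosynthesis with a median difference of -0.32 (adjusted p = 0.288 with an estimated correlation), were not called with an estimated correlation. The replicate block called 12 lists, adding apoptosis regulators and mitochondrial ribosomal proteins (adjusted p of 0.034 and 0.038). With an estimated correlation and no block, neither of the added lists was called. The count was 1 with only the HCT15 arrays fitted, 41 with arrayWeights and 2 without both WT arrays numbered 1. Leaving out single arrays gave 3 (WT Tet number 1) to 43 (WT Tet number 3), with 20, 6 and 7 without WT untagged number 1, untagged number 2 and Tet number 2, and 6, 3, 5 and 4 without Y330H Tet number 1, untagged number 2, Tet number 2 and Tet number 3.

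**Figure D2:**
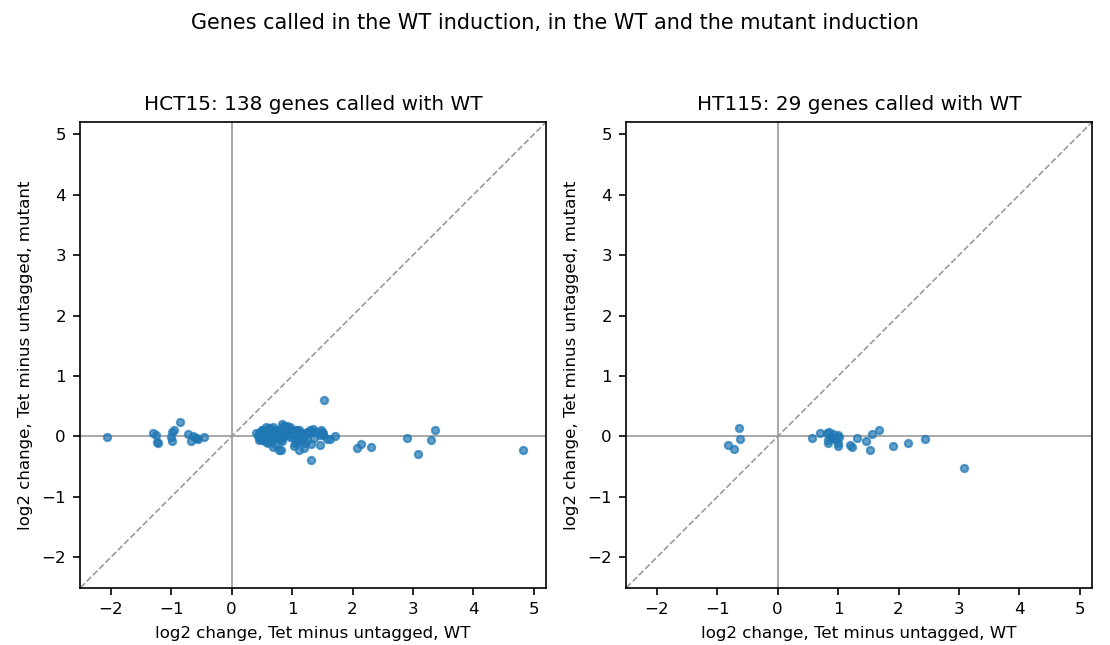
Log2 change (Tet minus untagged) of the 138 genes called in the HCT15 WT induction and the 29 called in the HT115 WT induction, 1 point per gene, with the change under WT on the horizontal axis, that under the mutant form on the vertical axis and a dashed line where both are equal. The changes under the mutant form range from -0.39 to 0.60 in HCT15 and from -0.52 to 0.14 in HT115.

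In HT115, wild-type MLK4 was followed by a rise of 25 genes and a fall of 4, and 13 of the rises were at least 2-fold. At an unadjusted p under 0.05 the balance was the reverse, with 438 genes higher and 1099 lower. MXRA5, a matrix remodelling protein, rose most, by 3.08 on the log2 scale (SE 0.38, 8.46-fold), from 3.84 ± 0.42 to 6.92 ± 0.50 (SD, n = 3). The matrix metalloproteinase MMP7 rose by 2.44 (SE 0.35, adjusted p = 0.00239), from 7.94 ± 0.45 to 10.38 ± 0.20. FILIP1L rose by 2.16, the membrane protein EMP3 by 1.90, the microtubule protein MAP1B by 1.68 and the adhesion molecule MCAM by 1.56. CREB5, a transcription factor that pairs with JUN, rose by 1.53, the guidance factor NTN4 by 1.46, the immune ligand HHLA2 by 1.31 and DUSP10 by 1.23. The falls were in VN1R5 (by 0.82), FGF14 (by 0.72), PLA2G3 (by 0.64) and ATP4A (by 0.63). JUN had a change of 0.32 (SE 0.16, adjusted p = 0.668), CDKN1A of 0.25 (SE 0.31), CDKN2B of 0.20 (SE 0.15), MAPK8 of 0.01 and MAPK9 of -0.02, none past the test. The count of 29 was 7 among the brighter genes, where 50% of the genes were tested, and was 100 with arrayWeights and 186 with a replicate block, although the HT115 arrays were not taken as pairs. It was 17, 15, 15 and 13 without the untagged arrays numbered 1, 2 and 3 and the Tet array numbered 3.

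**Figure D3:**
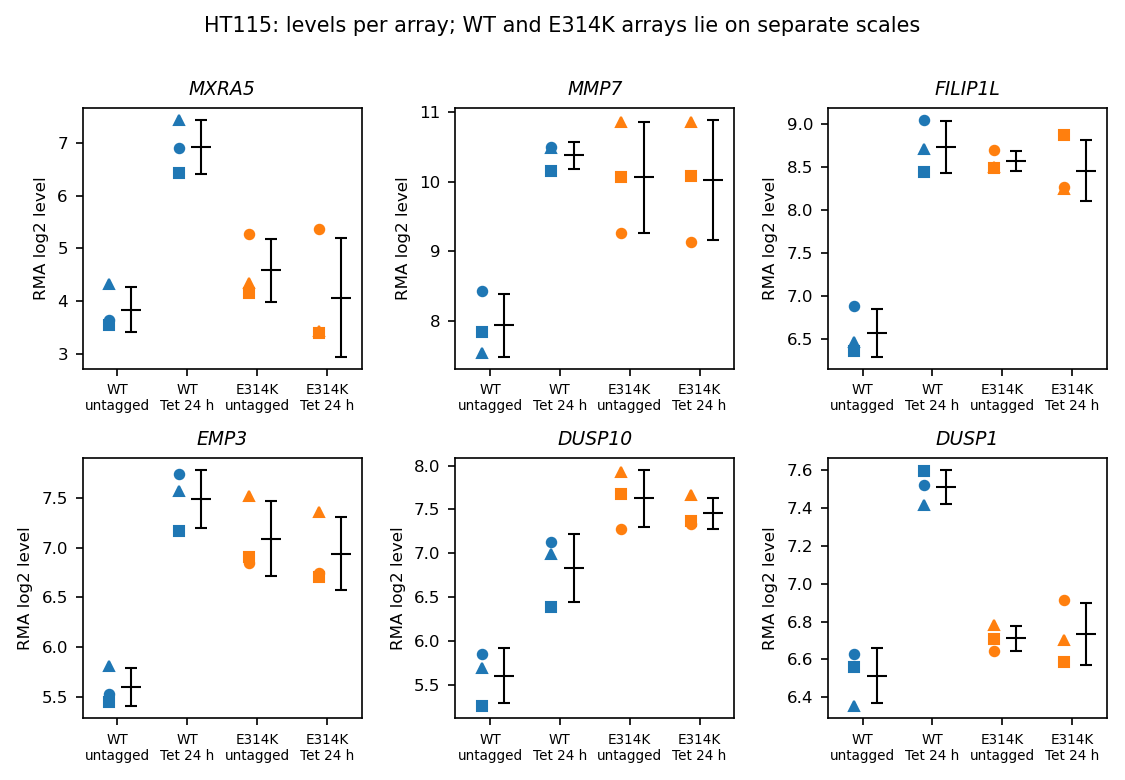
RMA log2 levels of 6 genes (vertical axes, each with its own range) in the 4 HT115 groups, 1 point per array with its shape set by the replicate number, and bars for the mean and SD of n = 3 arrays. The WT and E314K arrays lie on separate normalization scales, so only Tet and untagged arrays of 1 form can be compared, and MXRA5 lies at 6.92 ± 0.50 in the Tet-tagged against 3.84 ± 0.42 in the untagged WT arrays.

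The AP-1 targets also shifted upward in HT115 with WT. Of 24 measured members, DUSP10, the stromelysin MMP10 (by 1.02) and DUSP1 (by 1.00) rose over all genes, and 6 rose adjusted over the list alone. The list's median change was 0.29 (adjusted p = 9.6e-10, and adjusted p = 0.0400 with an estimated correlation), and it was the only one of 8 called lists that was called with an estimated correlation. The AP-1 family list had no called member and an upward shift (adjusted p = 0.00064, and adjusted p = 0.134 with an estimated correlation). Its members with the smallest p were MAFF (0.92, adjusted p = 0.260) and ATF3 (1.55, SE 0.51, adjusted p = 0.414). ATF3 went from 6.80 ± 0.14 to 8.35 ± 0.19 (SD, n = 3), and its SE pools the spread of all 8 groups. The ATF4 list shifted upward with a median of 0.21 and no called member (adjusted p = 1.7e-06, and adjusted p = 0.480 with an estimated correlation). GDF15 of this list had a change of 1.25 (SE 0.48 from the same pooled spread, adjusted p = 0.494), from 8.93 ± 0.14 to 10.18 ± 0.25 (SD, n = 3). The list of epithelial junction genes (adjusted p = 0.00064), that of p53 targets (0.0156), ERK feedback genes (0.0156) and ribosome biogenesis genes (0.0468) shifted upward and that of goblet markers downward (0.0360). None of these held with an estimated correlation (adjusted p of 0.134, 0.147, 0.461, 0.683 and 0.507). PMEPA1, a TGF-beta target, rose by 1.01 in a list that did not shift (adjusted p = 0.103). Cholesterol biosynthesis genes had a median of -0.11 (adjusted p = 0.158) and G1/S genes one of -0.04 (adjusted p = 0.768).

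**Figure D4:**
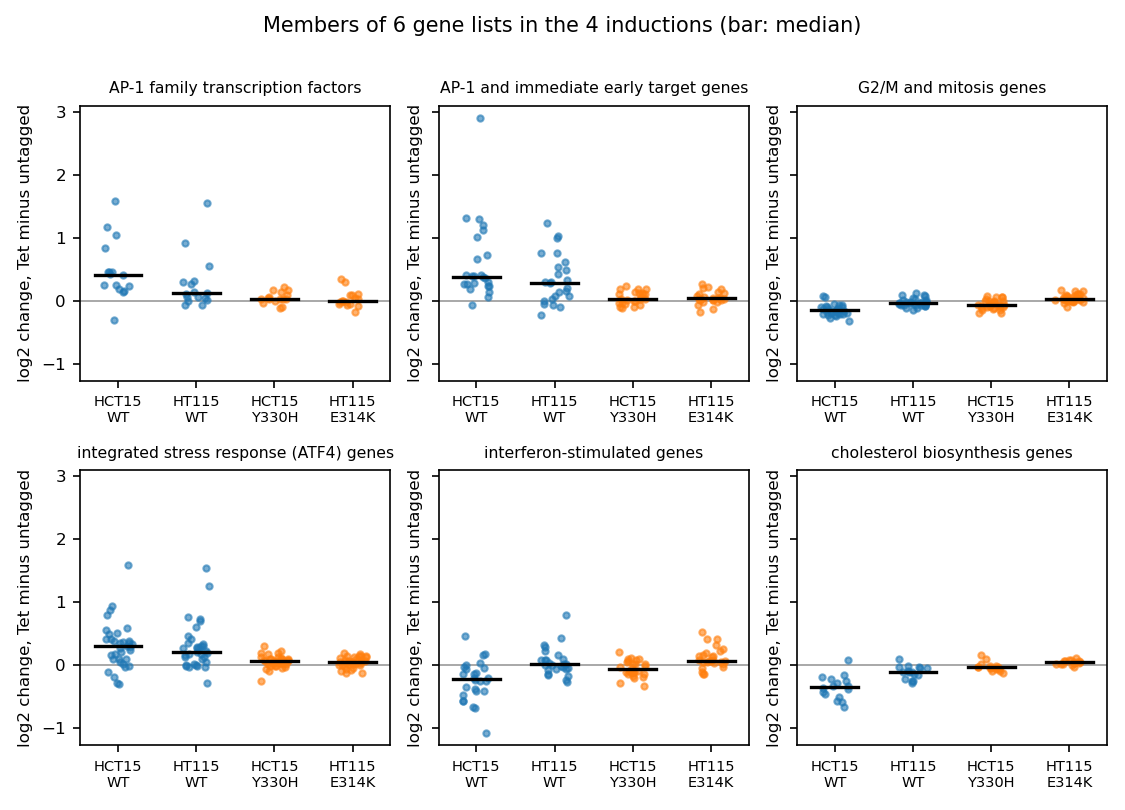
Log2 change (Tet minus untagged, vertical axis) of the measured members of 6 gene lists in the 4 inductions, 1 point per gene, with a bar at the median. The medians of AP-1 and immediate early target genes are 0.38 in HCT15 WT and 0.29 in HT115 WT.

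No gene was called by limma when E314K was induced in HT115, with 313 genes at an unadjusted p under 0.05 (1.6% of genes) and the smallest adjusted p at 0.0894 for IYD, a dim gene with a change of 0.74 (SE 0.12). A single gene was called with arrayWeights or without the E314K Tet array numbered 1 or 2. The other genes with the smallest p were GPR82, LOC105378311, EVI2A and ADAM28, with changes from -0.71 to -0.41. JUN had a change of -0.06 (SE 0.16), CDKN1A of 0.12, CDKN2B of -0.17, MAPK8 of -0.06 and MAPK9 of 0.06. The interferon list was called upward with a median of 0.07 (adjusted p = 0.0092, and adjusted p = 0.785 with an estimated correlation). The test of the difference between WT and E314K, which compares changes within separate scales, called MXRA5 (3.60, SE 0.53, adjusted p = 0.0106), FILIP1L (2.26) and EMP3 (2.05), all larger with WT. The AP-1 target list had a median difference of 0.21 (adjusted p = 3e-06, and adjusted p = 0.205 with an estimated correlation). This count of 3 was 0 among the brighter genes, 6 with all probe sets or arrayWeights and 8 with the mean of probe sets. It was 0 without WT untagged number 2 or WT Tet number 3, 1 without WT untagged number 1 or 3 or E314K Tet number 2, and 6 without WT Tet number 2.

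The WT inductions of the 2 lines share no arrays, so their calls could be set against each other. Both were tested with the same residual spread per gene, which favours calls of the same low-spread genes in each. The lists are therefore not fully independent, and the values below for independent lists may overstate the excess. The rises shared 5 genes, against 0.153 for independent lists (Fisher's exact test across genes, one-sided p = 3.8e-07, genes not being independent replicates). These were CREB5, DUSP1, DUSP10, ST3GAL6 and TRIB1, named as shared genes after their values were seen. Of the falls called by limma 0 were shared, and 1 (ATP4A) with an unadjusted p under 0.05 in HCT15. With an unadjusted p under 0.05 in HT115, 0 of the 17 falls in HCT15 were shared, against 0.945 for independent lists. Of the 121 rises in HCT15, 48 had an unadjusted p under 0.05 in the same direction in HT115, against 2.68 for independent lists. Changes correlated between the lines at Pearson's r of 0.357 and Spearman's rho of 0.356 across 19775 genes, and the change had the same sign in HT115 WT for 117 of the 138 genes called in HCT15 WT, most of which did not pass the test there. The same count was 92 in HT115 E314K and 76 in HCT15 Y330H. By comparison r was 0.177 between HCT15 WT and Y330H, 0.135 between HT115 WT and E314K, and 0.278 between HT115 WT and HCT15 Y330H. The difference between the WT inductions was called for 5 genes, and for 91 (37 higher and 54 lower in HCT15) with a replicate block, which only the HCT15 arrays bear out as pairs. CPA4 (4.53, SE 0.57), KRTAP4-1 (3.32), GPRC5A (2.78) and CORO2B (1.33) changed more in HCT15 and FILIP1L (-2.27, SE 0.33) more in HT115. Of the lists, AP-1 targets had a median difference of 0.26 (adjusted p = 0.0062, and adjusted p = 0.588 with an estimated correlation), and 8 were called of which 0 were called with an estimated correlation. The count of 5 was 0 among the brighter genes and without both HCT15 WT arrays numbered 1, 8 or 9 with other probe set rules, 8 with only the arrays compared and 43 with arrayWeights. Single arrays moved it to between 1 (HT115 WT Tet number 1 or untagged number 2) and 25 (HCT15 WT Tet number 3), with 3 without HCT15 WT Tet number 1 or untagged number 2 and 2 without HT115 WT untagged number 1, Tet number 2 or Tet number 3.

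The 2 engineered HCT15 versions differed before induction. In untagged arrays 669 genes were higher and 512 lower in WT than in Y330H, 163 and 137 of them at least 2-fold. Higher in WT were CCND2, a G1 cyclin (by 3.80, SE 0.71), the RNA-binding protein CELF2 (3.61), RNF182 (3.27), the receptor tyrosine kinase KIT (3.26) and the homeobox factor DLX1 (3.15). TMEM200A was lower in WT with a difference of -5.01 (SE 0.43), from 9.16 ± 0.77 in Y330H to 4.15 ± 0.77 in WT (SD, n = 3). The tetraspanin TSPAN8 (-4.93), the secretory cell protein AGR2 (-4.13), TM4SF1 (-4.07) and LXN (-3.80) were also lower. Over 15 alternatives TM4SF1 ranged from -5.037 to -1.789 and CELF2 from 1.895 to 4.305, and both kept the call in all. JUN, chosen here after its value was seen, was higher in WT by 0.57 (SE 0.16, adjusted p = 0.0363). The spread in WT was wide for several of these, with an SD of 2.68 for TSPAN8 and 2.15 for AGR2. The ACTB 3' to 5' difference moved with this comparison, at 0.728 ± 0.388 in WT and 0.429 ± 0.027 in Y330H. The count of 1181 was 170 with only these 6 arrays fitted, 3728 with arrayWeights and 713 without both WT arrays numbered 1. It was 673, 708 and 629 without WT number 1, WT number 2 and Y330H number 3.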

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

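The tests below on tetracycline, noise, RNA integrity, mislabelling and scale were chosen after the results they bear on had been seen, whereas the counts over other splits, the test of chromosome dosage and that of a smaller response were set beforehand. For chromosome dosage and the smaller response, a further requirement was added after the result was seen, as described with each test.

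The WT induction differed between the lines by a direct test of the difference for 5 genes. CPA4 (4.53), KRTAP4-1 (3.32), GPRC5A (2.78) and CORO2B (1.33) changed more in HCT15, and FILIP1L (-2.27) changed more in HT115. Of 100 splits that reassign the tetracycline tags within each line, 12 called at least 5 genes, and the highest other split called 356. Of the 80 splits that part the HCT15 pairs, a set chosen after the result was seen, 14 did (highest other 158), 12 of which besides the real one keep the HCT15 tags in place. Of the 100 drawn splits, 11 keep the HCT15 tags in place and so keep the change in that line, and 7 of these called at least 5 genes. The share of splits therefore cannot decide whether chance gave this count, and chance is not excluded.

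Probe sets without a single gene name, which no comparison above uses, also moved with WT. Of 13522 such probe sets, 33 were called in the HCT15 WT induction (32 higher) and 2 in the HT115 WT induction, against 0 in either mutant induction by limma. At an unadjusted p under 0.05 there were 776 and 1092 with WT, and 628 and 509 with Y330H and E314K.

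The first pattern weighed is that WT inductions called rises while limma called 0 genes in the mutant inductions (614 and 313 at an unadjusted p under 0.05). Tetracycline itself would move the same genes with the mutant forms. The 121 rises in HCT15 had a median change of 0.013 with Y330H (95% bootstrap interval -0.006 to 0.037) against 0.874 with WT, and the 25 rises in HT115 one of -0.038 with E314K (-0.108 to -0.006) against 1.006, which argues against tetracycline as the whole source. These intervals resample genes, so they ignore the correlation between genes and do not measure the spread between arrays. The median gene SD within groups of the mutant arrays was 1.07 times that of WT in HCT15 and 1.06 times in HT115. All inductions were tested with the same residual spread per gene. Noisier mutant arrays would thus widen the WT tests as much, so this ratio cannot weigh noise as the source. A difference in activity between wild-type and mutant MLK4 remains open as a hypothesis, as does failed induction of the mutant proteins, which the MAP3K21 probe set does not show. The form of MLK4 also cannot be separated from the engineered version that carried it. In HCT15 these versions already differed for 1181 genes in untagged arrays.

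In the WT inductions 1 of the 10 splits of the 6 arrays, the real one, gave 138 genes in HCT15 (highest other 64) and 29 in HT115 (highest other 0), and 10 splits are too few for a share under 0.05. The real splits of the mutant inductions called 0 genes, which all 10 splits reach, with highest others of 753 for Y330H and 14 for E314K. The split of 753 points to a structure of the HCT15 Y330H arrays other than tetracycline. Among the 4 splits that part all 3 pairs, the highest other count was 0 in HCT15 WT and 0 in Y330H. For the difference between the HCT15 inductions 16 of 100 splits called at least 12 genes (highest other 551), and of the 32 splits that part all pairs 6 did (highest other 23), 5 of which besides the real one keep the WT tags in place. For the HCT15 difference, 12 other splits of the 100 keep the WT tags and so the WT change. Of these, 10 called at least 12 genes. The share of splits therefore cannot decide whether chance gave the HCT15 difference. For the HT115 difference 8 of 100 splits called at least 3 genes (highest other 18), and chance is not excluded for either. For the untagged HCT15 comparison the real count was 1181 in 1 of 10 splits, which are too few for a share under 0.05, and the highest other was 1.

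The second pattern is that HCT15 arrays with the same number deviate together. RNA integrity as the whole source of large single-gene differences in HCT15 WT is argued against by only 3 genes over 1.5 apart (log2, with and without Tet) between the pairs numbered 1 and 2, with ACTB values of 1.053 and 0.413, against 36 between those numbered 2 and 3, with 0.413 and 0.512. This count leaves out small changes of many genes, so it cannot weigh integrity as the source of the correlation itself. Mislabelled Y330H arrays as the pair numbered 3 are argued against by 100 genes that rose in the other pairs, with a median change of 0.624 in that pair (95% bootstrap interval 0.558 to 0.686), 1.086 in the others and 0.012 in Y330H. That interval resamples genes and ignores their correlation. For cell populations that differ in chromosome dosage, the variance of autosome medians between the Tet arrays numbered 3 and 1 was 0.000889, above all 1000 shuffles (highest 0.000438), which by the bound set beforehand counted for dosage. After that was seen, autosomes were found to move between numbers 2 and 1 as well (chromosome 19 by 0.153), so a correlation between Tet and untagged arrays for number 3 minus 2 was also required, which was 0.252 (0.922 for number 3 minus 1), and dosage and the quality of the arrays numbered 1 cannot be told apart.

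The third pattern is the lower count in HT115 WT (29) than in HCT15 WT (138), an order that reversed when only the arrays compared were fitted (24 against 6), while HCT15 WT had 35 without both arrays numbered 1. The median gene SD in HT115 WT was 0.796 times that in HCT15 WT. Since the main fit used the same residual spread per gene for both, this ratio cannot weigh noisier arrays as the source. A compressed scale is argued against by an SD over probe sets of 1.02 times that in HCT15 WT. For a smaller response in HT115, which stays open, over the 24 AP-1 and immediate early target genes fixed beforehand, the change in HCT15 exceeded that in HT115 by a median of 0.263 (95% bootstrap interval 0.106 to 0.313), which by the bound set beforehand counted for it. That bootstrap ignores the correlation between genes, and the list's difference had an adjusted p = 0.588 with an estimated correlation, which was required after the result was seen.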

How the results depend on the processing

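The added setting without both HCT15 WT arrays numbered 1 was chosen after seeing the data, and the cause of a moved value was not tested unless stated. The replicate block moved the counts of called genes to 961 (HCT15 WT), 186 (HT115 WT), 189 (HCT15 difference), 31 (HT115 difference) and 91 (WT between lines). It kept all genes of the unblocked fit in each. HT115 numbers were not taken as pairs, since own-number correlations were 0.594, 0.051 and 0.317 in E314K and 0.226, 0.188 and -0.005 in WT. Of these 6 numbers, E314K 2 and WT 3 correlated higher with another number. No block was fitted for untagged HCT15 WT against Y330H, which compares different blocks. With arrayWeights the counts were 1438 (HCT15 WT), 100 (HT115 WT), 1 (E314K), 41 (HCT15 difference), 6 (HT115 difference), 43 (WT between lines) and 3728 (untagged HCT15). Fitting only the arrays compared gave 6 (HCT15 WT), 1 (HCT15 difference), 8 (WT between lines) and 170 (untagged HCT15), with fewer residual degrees of freedom. HT115 WT lost as many degrees of freedom but stayed within 1.5 times its count, so their loss alone does not account for the fall in HCT15 WT. The median gene SD was 0.174 in untagged and 0.152 in Tet-tagged HCT15 WT arrays, against 0.118 and 0.141 in HT115 WT. The main HCT15 WT count thus rests on a spread pooled over all groups. Testing only the brighter genes gave 7 (HT115 WT), 0 (HT115 difference) and 0 (WT between lines). All probe sets gave 6 and 8, and the mean of probe sets 8 and 9, for the HT115 difference and WT between lines. Without both arrays numbered 1 the counts were 35 (HCT15 WT), 2 (HCT15 difference), 0 (WT between lines) and 713 (untagged HCT15). Leaving out 1 array gave 50 to 257 (HCT15 WT), 13 to 27 (HT115 WT), 0 to 0 (Y330H), 0 to 1 (E314K), 3 to 43 (HCT15 difference), 0 to 6 (HT115 difference), 1 to 25 (WT between lines) and 629 to 1279 (untagged HCT15). Quantile normalization, median centring and eBayes with trend and robust stayed within 1.5 times the count in each comparison. Y330H stayed at 0 throughout.

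With an estimated correlation the lists called were 2 of 14 (HCT15 WT), 1 of 8 (HT115 WT), 0 of 1 (E314K), 2 of 10 (HCT15 difference), 0 of 4 (HT115 difference) and 0 of 8 (WT between lines). With fry they were 5, 1, 0, 1, 0 and 0. The block gave 1 list for Y330H and 8 for the HT115 difference. With an unadjusted p in the second line 48 rises were shared by the WT inductions, and 1 by HCT15 WT and Y330H. With an unadjusted p in HCT15, 1 fall was shared by the WT inductions. Of 2584 values of 155 named gene results, 2171 stayed on their side of the threshold and 32 changed sign, none of them for a gene called under either setting. The 35 named genes called in the HCT15 WT induction kept their sign in each alternative that gave them a value (15 or 16 per gene), and 4 of them were called in each of these. Named called genes of the other comparisons also kept their sign throughout. Called in each alternative were 7 of 17 (HT115 WT), 1 of 10 (HCT15 difference), 0 of 3 (HT115 difference), 0 of 5 (WT between lines) and 6 of 10 (untagged HCT15). Alternatives for untagged HT115 WT against E314K were not run, as that comparison was not made. RMA gives no detection call, so signal over background is unknown and changes of dim genes are open to it.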

Other observations

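The tests on the squamous, actin and keratin-associated genes were set before their values were examined but after the genes that prompted them had been seen. The pair numbered 3 of HCT15 WT stood apart from the pairs numbered 1 and 2 in single genes, of which 6 were chosen here after their values were seen. No gene list was tested for this difference. TSPAN8 was higher by 4.49 in the untagged and by 4.74 in the Tet array than the mean of the other numbers, AGR2 by 3.73 and 3.30, TM4SF1 by 2.91 and 2.91, and VIL1, the brush border protein villin, by 2.80 and 2.87. CCND2 had differences of -3.35 and -2.48 and RNF182 of -3.04 and -2.45. TSPAN8, AGR2 and TM4SF1 were also lower in WT than in Y330H in untagged arrays, and CCND2 and RNF182 higher, so the pair numbered 3 lay on the side of Y330H for these genes while 97 of 100 genes that rose in the other pairs were higher with Tet in it.

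The 3 KRTAP genes that rose in HCT15, of 34 measured, lie in the keratin cluster of chromosome 17, near KRT20, which rose as well. Between KRT20 and KRTAP3-2 lie KRT23, KRT40 and KRTAP3-3, with changes of -0.066, -0.048 and -0.078. A shared change of the locus was tested as a hypothesis. The 20 measured genes nearest to KRTAP3-1, 10 on either side, had a median change of -0.045, within the range of random runs of genes (5th to 95th percentile -0.116 to 0.058), and only KRT20 and KRTAP3-2 among them were called. KRTAP1-5, next to KRTAP3-1, had a change of 1.045 that did not pass the test (limma adjusted p = 0.102). The median argues against a change of the whole locus, but it cannot see a change of only the nearest genes.

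A squamous programme was tested because S100A2 and 3 of the KRTAP genes rose. A list of 25 squamous and cornified envelope genes without those already seen had 19 measured members, of which 0 were called in HCT15 with WT. Their median was -0.15 (camera p = 0.288 with an estimated correlation, direction downward, 5 of 19 positive), so the list gave no sign of such a programme. Actin cytoskeleton genes under SRF and MRTF were tested because MICAL2 and CORO2B rose. With an estimated correlation, the 22 measured of 26 members shifted upward in HT115 with WT (camera p = 0.0138, median 0.10, 0 called by limma) and did not pass in HCT15 (camera p = 0.124, median 0.05, 12 of 22 positive, 1 called). For both lists a p of 0.05 or higher, or a downward direction, had been set beforehand as counting against the hypothesis, and the squamous list met both and the actin list the former. That reading was dropped after the results were seen, because a p that misses the threshold does not show that the genes stayed in place. The downward direction of the squamous list was not past its own test either, and the list left out the genes already seen to rise, so it cannot exclude the hypothesis.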
